A study of Homo sapiens
Mus musculus with 6 samples.

How the data were processed

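HT29, an established human colorectal adenocarcinoma cell line, was grown as subcutaneous tumours in nude mice for 4 weeks. The labels describe 6 tumours, 3 control and 3 overexpressing the mouse laminin alpha 1 chain, and the series' design text calls the tumours of a group independent. Per the labels' protocols, total RNA was extracted with TRI Reagent, and Illumina TruSeq libraries were made from oligo-dT purified mRNA with random primers. No step that keeps the strand is described, so antisense and overlapping genes cannot be separated. The submitters' processing notes name TopHat2, Cufflinks and the builds hg38 and mm10. The roles, versions and options of these tools, and how human and mouse reads were kept apart, are not given in the sources used here.

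The authors deposited 1 gene table per species, with the column names of a Cuffdiff gene comparison per the file headers. Each gene has 1 signal value for the control group and 1 for the laminin group, set by the authors with no stated scale. A log2 ratio of the laminin over the control value, deposited by the authors, stands beside them. The authors' table also holds an unadjusted p-value and, for mouse genes, a q-value, per the file headers. The human table lists 63652 genes, of which 25838 carry a test, 37795 were not tested, 16 were set aside for excess data and 3 failed. The mouse table lists 42979 genes, of which 14339 carry a test and 28640 do not. It mixes 23316 entries on one style of chromosome names with 19663 entries on another, and the latter hold no signal. Another line of the mouse table had its cells shifted by 1 column and was left out. The mouse comparison was present in several copies with the same values, and it was used once.

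The deposited signal, in units of 1000000, sums to 893.067 and 890.561 in the human table for control and laminin tumours, and to 968.943 and 951.036 in the mouse table. These sums are far above those of usual FPKM. The minimum of 1 FPKM and the FPKM levels fixed before the data were examined therefore had no counterpart. Levels are given instead as parts per 1000000 of a table's summed signal (ppm), with 1 factor per table (the mean of both groups' sums), so that every ratio stays as deposited. The minimum became a mean level of 1 ppm over both groups. Because each species has its own scale, levels of human and mouse genes are not compared for size, except in checks for reads counted under the wrong species. The share of mouse reads per tumour, planned for count data, was not computed.

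The values were also examined for their steps. Among the 2000 values tested per group, up to 25 reads, 93.2% (control) and 91.8% (laminin) of the mouse values were whole-number sums of 3 step sizes, against 3.95% and 0.700% for values shifted off the steps. In the human table the shares were 71.9% and 71.4%, against 1.90% and 2.05%. Each step was taken as the worth of 1 read in 1 tumour of the group. Genes at a single mouse control step spanned loci of 83 to 911588 bases, so the values follow read numbers with no correction for gene length. A larger step means a shallower library. The largest over the smallest step was 1.02 among mouse control tumours and 2.47 among mouse laminin tumours, and 1.08 in both human groups. If each library had been scaled to the same total, the steps would correspond, in units of 1000000 mouse reads, to 2.24, 2.27 and 2.29 in control tumours and to 2.06, 3.38 and 1.37 in laminin tumours. On the same condition the human table would rest on 27.3, 29.2 and 29.6 in control tumours and on 28.9, 31.1 and 29.1 in laminin tumours, in the same units of reads. These depths are estimates on that condition, with an assumed total above the summed signal of each group. On the summed signal itself they would be lower, more so in the human table. At the same level in ppm a host gene rests on fewer reads than a human gene, 1 read being worth 0.103 to 0.254 ppm in the mouse table and 0.0120 to 0.0137 ppm in the human table. Whole reads per tumour could be separated only for low genes, so no count test was run.

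Only group values exist in these tables, so the main test is the authors' own, as fixed for that case before the data were examined. No SD or standard error between tumours can be given. Mouse genes were called at an authors' q-value under 0.05. Human genes carry no q-value in the table used, so the authors' p-values were adjusted by the Benjamini-Hochberg method over the 25838 tested genes. The same adjustment of the mouse p-values differed from the deposited q-values by at most 0.000307. The smallest p in the authors' deposited table is 5e-05, shared by 1067 human and 301 mouse genes, so genes cannot be ranked beyond it.

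Gene lists were fixed before the data were examined, 17 for the human and 24 for the mouse table. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Exact two-sided Fisher tests compared the called members, per direction, with the other tested genes at the level minimum (15565 human and 13757 mouse genes). Benjamini-Hochberg adjustment covered both directions of all lists of a table (34 human and 46 mouse tests). These tests run across genes, which are not replicates. Each list's median log2 ratio was also placed among 10000 random lists of the same size matched on mean level, as a description of these libraries. Orthologs were paired by symbol, ignoring case. Genes named in the text are the laminin, VEGFA, CXCR4, CXCL12 and integrin genes fixed beforehand, the 10 largest rises and falls per table among called genes with at least 1 ppm in the higher group, and up to 4 members per list with the smallest p. Predicted genes, clone names, pseudogenes, ribosomal, histone, small RNA and immunoglobulin genes were skipped. Some genes that this rule takes are not reported here. Other genes named below were chosen after their values were seen and serve as examples of a count. A gene at 0 in a group is described as listed at 0 and given no fold.

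The calling and list steps were tested on simulated data with changes of log2 2. Among 15536 simulated human genes they recovered 100 of 100 raised and 100 of 100 lowered genes with 9 false calls, and among 13591 mouse genes 100 of 100 and 100 of 100 with 11 false calls. They called 0 of 20 unchanged lists in either table. The simulated changes were large beside the simulated noise, the p-values came from that noise, and genes listed at 0 were left out. Full recovery was therefore near certain. It shows that the steps ran as written and gives no measure of the power of the authors' test. Alternatives were a level minimum of none, 1 or 5 ppm, p-values adjusted only over genes at the minimum, a threshold of 0.01, changes of at least 2-fold, ratios centred on the median gene, and a pseudocount of 0.1 or 1 for ratios. Leaving out genes listed at 0, and leaving out fat, muscle and skin genes, were alternatives added after the data were seen.

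Mouse positions are those of the deposited table (mm10 per the submitters' processing notes), counted from 1. Human positions are not given, because the table's positions overlapped GRCh38.p14 positions for only 16.1% of 30951 genes matched by symbol. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.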

Results

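Gene expression was compared between 3 control HT29 tumours and 3 HT29 tumours overexpressing the mouse laminin alpha 1 chain, a subunit of basement membrane laminin, to see what the added chain does to colorectal tumours. In a xenograft the human RNA comes from the grafted cancer cells, and the mouse RNA comes from the host stroma together with the mouse transgene. Each species had its own table with 1 value per group, given here as parts per 1000000 of the table's summed signal (ppm). There is no spread between tumours to set beside these values, and significance is that of the authors' test.

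Mouse Lama1, the overexpressed gene (mm10 chromosome 17, 67697265 to 67822645), stood at 4.75 ppm in control tumours and 1077 ppm in laminin tumours, 227-fold higher, with q = 0.00238 in the authors' deposited table. The Lama1 levels are parts of the mouse signal, which is that of the host and the transgene together. They therefore also depend on the host share of each tumour, which was not computed. Human LAMA1 (ENSG00000101680), on the separate human scale, had 1.01 and 0.978 ppm, and its p was 0.888 in the authors' deposited table. VEGFA (ENSG00000112715), the main growth factor of blood vessels, rose 1.63-fold in the tumour cells, from 313 to 512 ppm, with p = 5e-05 in the authors' deposited table. Host Vegfa (chromosome 17, 46016993 to 46032377) had 154 ppm in control and 277 ppm in laminin tumours and missed the threshold, at q = 0.0590 in the authors' deposited table. Its level was 1.81-fold higher, and it passed when adjusted over the list of host angiogenic factors alone. The chemokine receptor CXCR4 (ENSG00000121966) was measured at 63.1 and 63.3 ppm in the tumour cells, with p = 0.970 in the authors' deposited table. Host Cxcr4 (chromosome 1, 128588199 to 128592299) was at 85.6 and 122 ppm, with p = 0.0411 and q = 0.442 in the authors' deposited table. The CXCR4 ligand Cxcl12 (chromosome 6, 117168535 to 117181368) had 354 and 318 ppm in the host and did not pass the test, and human CXCL12 was listed at 0 in both groups.

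None of the 4 integrin chains fixed beforehand passed the test over all genes in either species. In the tumour cells the levels in control and laminin tumours were 53.5 and 81.2 ppm for ITGA2, 416 and 393 ppm for ITGA6, 391 and 394 ppm for ITGB1 and 514 and 482 ppm for ITGB4. In the host they were 7.67 and 4.97 ppm for Itga2 (chromosome 13, 114835912 to 114932041), 92.7 and 75.3 ppm for Itga6 (chromosome 2, 71787083 to 71856758), 1412 and 1702 ppm for Itgb1 (chromosome 8, 128685654 to 128733579) and 23.9 and 13.3 ppm for Itgb4 (chromosome 11, 115974725 to 116012719). Unadjusted, ITGA2 had p = 0.0135 in the authors' deposited table, and its adjusted p was 0.125 over all genes and 0.0426 over its list alone.

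In the tumour cells, interferon response, hypoxia, angiogenic, WNT and NF-kB genes rose in laminin tumours, and cell cycle and cholesterol synthesis genes fell. Of 25838 human genes tested, 2087 differed at an adjusted p under 0.05, 1455 of them higher and 632 lower in laminin tumours. At 1 ppm or more, 1229 of 15565 were higher and 574 lower. The median human gene differed by a log2 ratio of -0.02. Of the higher genes 122 were listed at 0 in control tumours, and 109 of these had at most 25 reads in laminin tumours. Of the lower genes 39 were listed at 0 in laminin tumours.

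DMBT1, a secreted scavenger receptor protein of mucosal surfaces, rose 251-fold, from 0.257 to 64.4 ppm, or 52.1-fold with 1 ppm added to both levels. The other large rises among human genes included the gap junction gene GJA1 (0.128 to 4.80 ppm), the homeobox gene HOXD13 (0.142 to 3.34 ppm), the DNA sensor IFI16 (0.580 to 12.2 ppm), the Paneth cell defensin DEFA6 (0.393 to 6.10 ppm) and the complement regulator CFI (1.42 to 21.3 ppm). WIPF3 went from 0.185 to 3.60 ppm. SNCAIP and SYT4 were listed at 0 in control tumours and at 1.58 and 1.05 ppm in laminin tumours. Among the falls were AUTS2 (51.3 to 1.77 ppm), the lysosomal enzyme GALC (16.3 to 0.611 ppm) and the transporter SLCO1B3 (7.89 to 0.420 ppm). The gastric-type genes VSIG1 (91.1 to 4.05 ppm), MUC5AC (18.9 to 1.71 ppm) and CLDN18 (2.72 to 0.325 ppm) also fell, as did NEBL (35.4 to 3.48 ppm), TRAT1 (4.71 to 0.435 ppm) and the transcription factor gene IRF8 (2.62 to 0.178 ppm). Each of these genes had p = 5e-05 in the authors' deposited table except GJA1, with p = 0.00025, and IRF8, with p = 0.00395.

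Interferon response and inflammatory genes rose in the tumour cells. Of 26 tested members 21 rose and 0 fell, and adjusted over the list alone 26 rose. Their median log2 ratio was 0.98, and the exact two-sided Fisher test gave an adjusted p of 4.55e-18 over 34 tests (Benjamini-Hochberg, across genes, which are not replicates). IFITM1 went from 14.5 to 115 ppm, IFI44L from 5.70 to 35.7 ppm, XAF1 from 6.23 to 25.6 ppm and the antiviral enzyme gene RSAD2 from 3.28 to 13.1 ppm. IFITM1 has close paralogs, which makes its own value uncertain. Of the myeloid markers counted in the human table, ITGAM (1.11 to 3.32 ppm) and CD14 (0.981 to 2.78 ppm) rose, and CD68 had 18.9 and 41.4 ppm and did not pass. Of 14 NF-kB and inflammatory genes 7 rose and 0 fell (8 rose adjusted over the list alone), with a median log2 ratio of 0.56 and an adjusted Fisher p of 1.91e-04. These included TNFAIP2 (1.96 to 35.9 ppm), complement factor CFB (20.6 to 72.4 ppm), lipocalin LCN2 (35.5 to 73.1 ppm) and the NF-kB inhibitor TNFAIP3 (6.77 to 13.7 ppm). Among 8 chemokine axis genes 3 rose, namely CX3CL1 (1.33 to 5.81 ppm), CCL20 (1.45 to 4.13 ppm) and CXCL1 (1.74 to 3.46 ppm), with 5 higher and 1 lower adjusted over the list alone and an adjusted Fisher p of 0.0691. At 5 ppm or more 0 of 3 measured chemokine axis genes passed, and the list median turned from 0.76 to -0.04.

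Genes induced by low oxygen rose in the tumour cells. Of 25 hypoxia genes 12 rose and 0 fell (16 rose adjusted over the list alone), with a median log2 ratio of 0.47 and an adjusted Fisher p of 1.25e-06. The collagen prolyl hydroxylase P4HA2 went from 86.8 to 259.6 ppm, carbonic anhydrase CA12 from 198 to 405 ppm and NDRG1 from 2174 to 3752 ppm. Carbonic anhydrase CA9, another hypoxia marker, had 198 and 189 ppm and did not pass. Of 15 angiogenic factor genes 9 rose and 0 fell, and 9 rose adjusted over the list alone, with a median log2 ratio of 0.61 and an adjusted Fisher p of 3.19e-06. Of these 9, VEGFA and ADM also stand in the hypoxia list and CXCL1 in the chemokine list. The others included PDGFC (9.66 to 20.1 ppm), the endothelin gene EDN1 (9.13 to 18.3 ppm), PDGFB (7.26 to 13.4 ppm) and EFNA1 (102 to 177 ppm). Of 17 glycolysis genes 3 rose, PGK1 (941 to 1271 ppm), ALDOA (1157 to 1546 ppm) and the lactate exporter SLC16A3 (61.7 to 119 ppm), and 3 rose adjusted over the list alone. The adjusted Fisher p for glycolysis was 0.349, while 16 of the 17 ratios were above 1 and the list median, a log2 ratio of 0.20, lay at percentile 99.97 of random lists matched on level.

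Proliferation and cholesterol synthesis genes fell in laminin tumours. Of 26 cell cycle genes 21 fell and 0 rose (25 fell adjusted over the list alone), with a median log2 ratio of -0.51 and an adjusted Fisher p of 1.05e-24. E2F1 went from 59.6 to 37.3 ppm, the replication helicase gene MCM4 from 332 to 208 ppm, RRM2 from 178 to 113 ppm and the mitotic kinase gene AURKA from 109 to 70.5 ppm. Of 20 cholesterol synthesis genes 7 fell and 0 rose (13 fell adjusted over the list alone), with a median log2 ratio of -0.35 and an adjusted Fisher p of 3.10e-05. The squalene epoxidase gene SQLE went from 683 to 491 ppm and INSIG1 from 202 to 147 ppm. Of 19 immediate early and stress genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), and the adjusted Fisher p for the rise was 0.00173. The risers included the chaperone gene HSPH1 (366 to 603 ppm), the phosphatase gene DUSP1 (14.4 to 25.3 ppm) and HSPA1B (70.5 to 104 ppm), which shares reads with its near copy HSPA1A and is uncertain. EGR1 fell from 75.8 to 26.3 ppm.

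WNT target and intestinal stem cell genes rose, while epithelial junction and intestinal differentiation genes moved both ways. Of 17 WNT and stem cell genes 8 rose and 1 fell (9 and 3 adjusted over the list alone), with a median log2 ratio of 0.67 and an adjusted Fisher p of 1.07e-04. At 5 ppm or more 4 of 12 rose, with a median of 0.29 and an adjusted Fisher p of 0.0376. NKD1 (0.282 to 2.03 ppm), EPHB2 (0.339 to 1.95 ppm) and NOTUM (0.975 to 2.45 ppm) rose from low levels, and AXIN2 went from 50.3 to 96.5 ppm. Against the rise of the list, its member DKK1 fell from 11.8 to 5.42 ppm. Adjusted over the list alone, MYC (208 to 163 ppm) and CCND1 (244 to 190 ppm) were lower too. Of 28 epithelial junction and intestinal differentiation genes 6 fell and 5 rose (8 and 5 adjusted over the list alone), and the adjusted Fisher p was 0.00174 for the falls and 0.202 for the rises. The intestinal transcription factor gene CDX2 (19.6 to 67.8 ppm), FABP1 (41.8 to 144 ppm) and alkaline phosphatase ALPI (0.768 to 2.64 ppm) rose. Beside MUC5AC, the mucin MUC2 (648 to 365 ppm) and CEACAM6 (1047 to 324 ppm) fell. The junction gene CDH1 had 714 and 772 ppm and EPCAM 1041 and 1033 ppm, and neither passed the test.

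The remaining human lists did not pass the Fisher test, although 3 of their medians lay high among random lists matched on level, at percentile 99.7 for laminin chains and integrins (median log2 ratio 0.14), 99.6 for epithelial to mesenchymal transition genes (0.46) and 99.88 for host stroma genes (1.13). Unfolded protein response, p53 target and mitochondrially encoded genes lay at percentiles 76, 78.8 and 29.3. Of 19 laminin chain and integrin genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with adjusted Fisher p of 0.371 and 0.349. The laminin receptor BCAM went from 39.8 to 84.8 ppm, ITGA1 from 97.8 to 173 ppm and LAMB2 from 25.6 to 34.8 ppm, while LAMA3 was among the falls (74.1 to 54.2 ppm). Of 10 epithelial to mesenchymal transition genes 2 rose, TGFB2 (0.750 to 2.57 ppm) and TGFBI (33.9 to 77.5 ppm), and 2 rose adjusted over the list alone, with an adjusted Fisher p of 0.371. Of 23 unfolded protein response genes 2 rose (ATF3 and DNAJC3) and 2 fell (ASNS and CHAC1), the same counts as adjusted over the list alone, and of 17 p53 targets 3 rose (SESN1, BBC3 and CDKN1A) and 1 fell (AEN), or 4 and 1 adjusted over the list alone. The adjusted Fisher p for the rises was 0.995 and 0.349. None of 9 mitochondrially encoded genes passed the authors' test, either over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. MT-CO2, for example, had 5848 and 5352 ppm. Of 6 measurable host stroma genes read in the human table, 2 rose, the myeloid genes ITGAM and CD14, and 2 rose adjusted over the list alone, with an adjusted Fisher p of 0.214. These 2 genes did not rise in the host, where Itgam had 204 and 202 ppm and Cd14 went from 102 to 56.6 ppm.

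**Figure D1:**
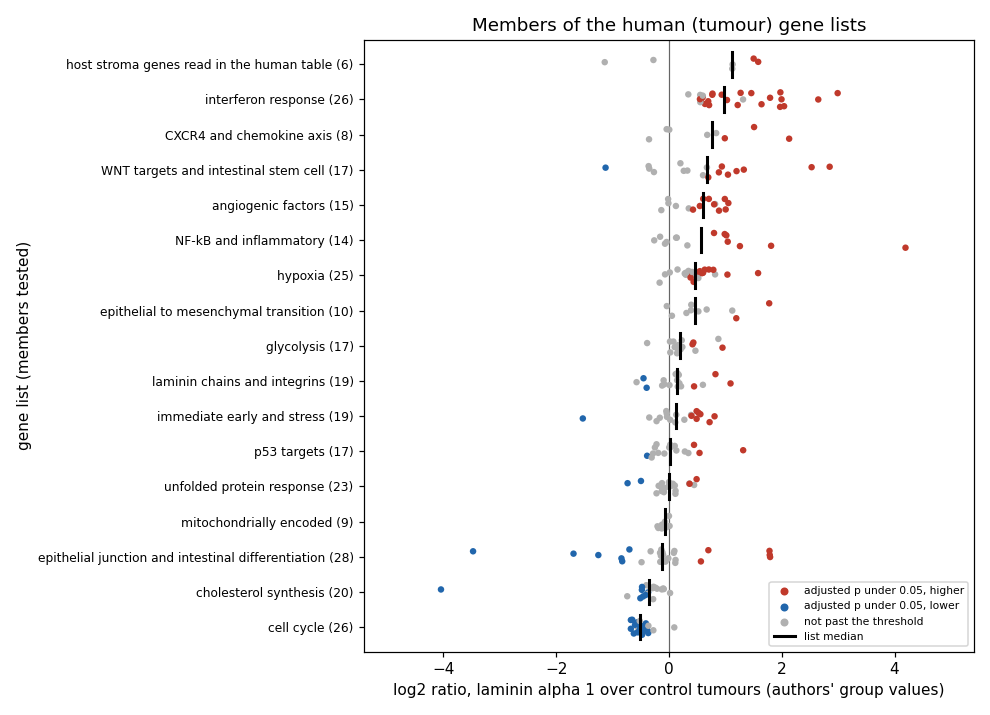
Each point is a tested member of a human gene list, placed on the x axis by its log2 ratio of laminin over control tumours, with the number of tested members beside each list on the y axis. Red and blue points passed an adjusted p under 0.05, grey points did not, and the black bar is the list median, at 0.98 for interferon response and -0.51 for cell cycle genes.

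In the mouse table, fat, skeletal muscle and skin genes were far lower in laminin tumours, and a smaller set of hypoxia, tip cell, angiogenic and interferon genes was higher. Of 14339 mouse genes tested, 508 passed the authors' q-value threshold, 83 higher and 425 lower in laminin tumours. At 1 ppm or more, 81 of 13757 were higher and 413 lower, and the median gene differed by a log2 ratio of -0.03. Of the lower genes, 143 were listed at 0 in laminin tumours.

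After Lama1, the largest rises in the mouse table included the cytokine Il11 (4.75 to 27.8 ppm), the costimulatory receptor Tnfrsf9 (6.60 to 37.2 ppm), the heme synthesis gene Alas2 (6.73 to 36.4 ppm), Gnpda1 (7.01 to 49.1 ppm) and Zfp949 (9.80 to 58.3 ppm). Trim30d (3.22 to 33.0 ppm) and Cwc22 (21.3 to 123 ppm) have close copies in the mouse genome and are uncertain. The angiotensin receptor Agtr2 and Tmem59l were listed at 0 in control tumours and at 3.67 and 1.72 ppm in laminin tumours. The 10 largest falls were all listed at 0 in laminin tumours. In control tumours the epidermal keratin Krt1 had 425 ppm and the liver protein gene Alb 159.8 ppm, Dsg1a 85.8 ppm, Hrnr 51.4 ppm, Cst6 50.6 ppm, Sprr1a 45.8 ppm, Krtap15 41.1 ppm, Krt6b 31.7 ppm, Sdr16c6 30.9 ppm and Stfa3 28.8 ppm. The control values of Hrnr and Krt6b were whole multiples of 1 control tumour's read step, at 332 and 205 reads. Such a value arises when that tumour holds all reads of the gene, so these levels need not be shared by the control tumours.

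By the read steps of the values, the 3 control tumours did not contribute equally to genes listed at 0 in laminin tumours. Of 195 such genes (1 ppm or more and up to 300 reads in control tumours) 61 had a control value that was a whole multiple of the same tumour's step and 0 of either other step, against 12, 6 and 16 of 7270 genes within 2-fold, and that tumour held 58.9% of the reads of the 67 low genes whose reads could be assigned, against 27.8% and 13.3% in the others. Of these 67 genes 34 had reads in all 3 control tumours and 14 in 1. Genes at least 16-fold lower and not at 0 leaned to the same tumour. Of 141 such genes in the same range 20 were whole multiples of its step, against 1 and 0 for the other steps. It held 64.0% of the reads of 8 assignable low genes, and 4 of these had reads in all 3 control tumours. No tested adipocyte or muscle list gene and 2 of the skin list were listed at 0. Of the list genes with up to 300 reads, 0 of 2 adipocyte genes (Lep and Pparg) and 1 of 4 skin genes (Lor, not Krt15, Sfn or Trp63) were whole multiples of that tumour's step, so these steps do not show which tumours carried the adipocyte and muscle lists. The counts below could not be repeated without 1 tumour, because the values are per group. Of 15 adipocyte genes 11 fell and 0 rose (13 fell adjusted over the list alone), with a median log2 ratio of -4.87 and an adjusted Fisher p of 4.41e-13 over 46 tests. Adiponectin (Adipoq) went from 288 to 6.56 ppm, carbonic anhydrase Car3 from 2468 to 87.4 ppm, the lipid droplet gene Cidec from 303 to 6.41 ppm and the brown fat gene Ucp1 from 98.6 to 2.67 ppm. Of 17 skeletal muscle genes 12 fell and 0 rose (14 fell adjusted over the list alone), with a median log2 ratio of -2.65 and an adjusted Fisher p of 1.14e-13. Muscle creatine kinase (Ckm) went from 611 to 46.8 ppm, the myosin gene Myh4 from 1301 to 120.1 ppm, Pvalb from 141 to 8.21 ppm and Tnni2 from 195 to 24.3 ppm. Of 17 skin and keratinocyte genes 5 fell and 0 rose (10 fell adjusted over the list alone), with a median log2 ratio of -7.26 and an adjusted Fisher p of 8.38e-04. Krt10 went from 447 to 2.94 ppm and Dmkn from 119.7 to 10.7 ppm. Together the adipocyte list held 0.932% of the mouse signal in control and 0.0462% in laminin tumours, the muscle list 0.726% and 0.127%, and the skin list 0.271% and 0.00535%. Among 6 measurable gut epithelial genes 2 fell, Cdh1 (34.0 to 3.44 ppm) and Cldn4 (7.73 ppm to listed at 0), and 2 fell adjusted over the list alone, with an adjusted Fisher p of 0.0636.

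Host hypoxia and vessel sprouting genes rose in laminin tumours, while general endothelial markers did not pass the test. Of 22 hypoxia and glycolysis genes 6 rose and 0 fell (8 rose adjusted over the list alone), with a median log2 ratio of 0.43 and an adjusted Fisher p of 3.66e-08. The glucose transporter Slc2a1 went from 98.6 to 263 ppm, Ero1l from 87.0 to 219 ppm and the lactate exporter Slc16a3 from 90.1 to 166 ppm. Of 14 tip cell and sprouting genes 4 rose and 0 fell (8 rose adjusted over the list alone), with a median log2 ratio of 0.69 and an adjusted Fisher p of 9.82e-06. These were Angpt2 (36.3 to 89.3 ppm), the tip cell marker Esm1 (23.9 to 58.4 ppm), adrenomedullin Adm (26.0 to 61.5 ppm), which is also 1 of the 6 hypoxia list rises, and placental growth factor Pgf (16.3 to 39.8 ppm). Of 21 angiogenic factor genes 3 rose, namely Angpt2, Adm and Pgf, which the tip cell list also holds, and 6 rose adjusted over the list alone, with an adjusted Fisher p of 0.00159. Of 22 endothelial genes 0 passed the authors' test, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median log2 ratio was 0.03, with Pecam1 at 370.3 and 373 ppm and Cdh5 at 332 and 362 ppm. Likewise 0 of 6 lymphatic endothelial genes passed, adjusted over the list alone or not, and 0 had an unadjusted p under 0.05, with Lyve1 at 124 and 145 ppm. All these levels are parts of the host signal. Because the share of mouse reads per tumour was not computed, they do not show the amount of vessels per tumour.

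Host interferon response genes also rose. Of 22 members 5 rose and 0 fell (9 rose adjusted over the list alone), with a median log2 ratio of 0.48 and an adjusted Fisher p of 1.75e-06. Ifit1 went from 29.0 to 71.0 ppm, Rsad2 from 27.9 to 64.7 ppm, Isg15 from 23.1 to 52.4 ppm and Oasl1 from 10.3 to 31.2 ppm. Of 21 laminin chain and basement membrane genes 2 rose, the transgene Lama1 and the matrix gene Fbln1 (112 to 200.0 ppm), with 2 higher and 1 lower adjusted over the list alone and an adjusted Fisher p of 0.0385. The list median lay at percentile 65.4 of random lists, and without the transgene the list had 1 rise among 20 members and an unadjusted Fisher p of 0.110. The partner chains Lamb1 (504 and 462 ppm) and Lamc1 (609.7 and 684 ppm) did not pass. Of 15 laminin receptor genes Itga7 fell, from 57.0 to 14.2 ppm, and 2 fell adjusted over the list alone (adjusted Fisher p = 0.993). Itga7 is an integrin of skeletal muscle, and its fall stood beside those of the muscle list.

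Most stromal and immune lists of the host did not pass the Fisher test, while several of their medians lay above nearly all random lists matched on level. The percentile was 100 for pericyte (median log2 ratio 0.35), erythroid (2.43) and chemokine axis genes, 99.98 for matrix (0.28), 99.8 for lymphoid (0.85) and 99.6 for macrophage genes (0.21), against 20.3 for fibroblast, 77.0 for neutrophil, 6.03 for cell cycle, 6.94 for nerve and 0.990 for mast cell and eosinophil genes. None of 21 fibroblast genes passed the authors' test, over all genes or adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 and a median log2 ratio of 0.04. Of 27 matrix and remodelling genes 1 rose and 1 fell, the latter being the collagenase Mmp13 (102 to 46.0 ppm), or 3 and 1 adjusted over the list alone. Among 17 pericyte and smooth muscle genes Actg2 rose (32.4 to 91.4 ppm) and Des, which the muscle list also holds, fell (331 to 138 ppm), the same counts as adjusted over the list alone. Among 24 macrophage genes arginase Arg1 rose (48.8 to 98.1 ppm) and Cd14 fell (102 to 56.6 ppm), and among 8 neutrophil genes Il1b rose (15.2 to 39.5 ppm) and Lcn2 fell (31.5 to 3.47 ppm), again 1 and 1 adjusted over the list alone in both. Of 6 mast cell and eosinophil genes Cpa3 fell (47.4 to 19.2 ppm), and 1 fell adjusted over the list alone. Of 5 erythroid genes Alas2 rose, and 1 rose adjusted over the list alone. Adjusted Fisher p for the rises in the matrix, pericyte, macrophage, neutrophil and erythroid lists was 0.485, 0.366, 0.468, 0.193 and 0.134, and for the mast cell fall 0.513.

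None of 23 chemokine axis genes passed the authors' test, over all genes or adjusted over the list alone, while 5 were higher and 0 lower at an unadjusted p under 0.05, and 21 of the 23 had a ratio above 1 with a median log2 ratio of 0.34. Among 9 lymphoid genes 0 passed over all genes, 1 was higher adjusted over the list alone and 1 was higher at an unadjusted p under 0.05, with Cd4 at 9.79 and 26.9 ppm. Among 24 host cell cycle genes 0 passed over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05, with a median log2 ratio of -0.20. Of 9 nerve and Schwann cell genes 0 passed over all genes or adjusted over the list alone and 1 was higher at an unadjusted p under 0.05. No mitochondrially encoded gene of the list was found in the mouse table. A step of 1 read was worth 0.103 to 0.254 ppm in the laminin tumours of the mouse table.

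**Figure D2:**
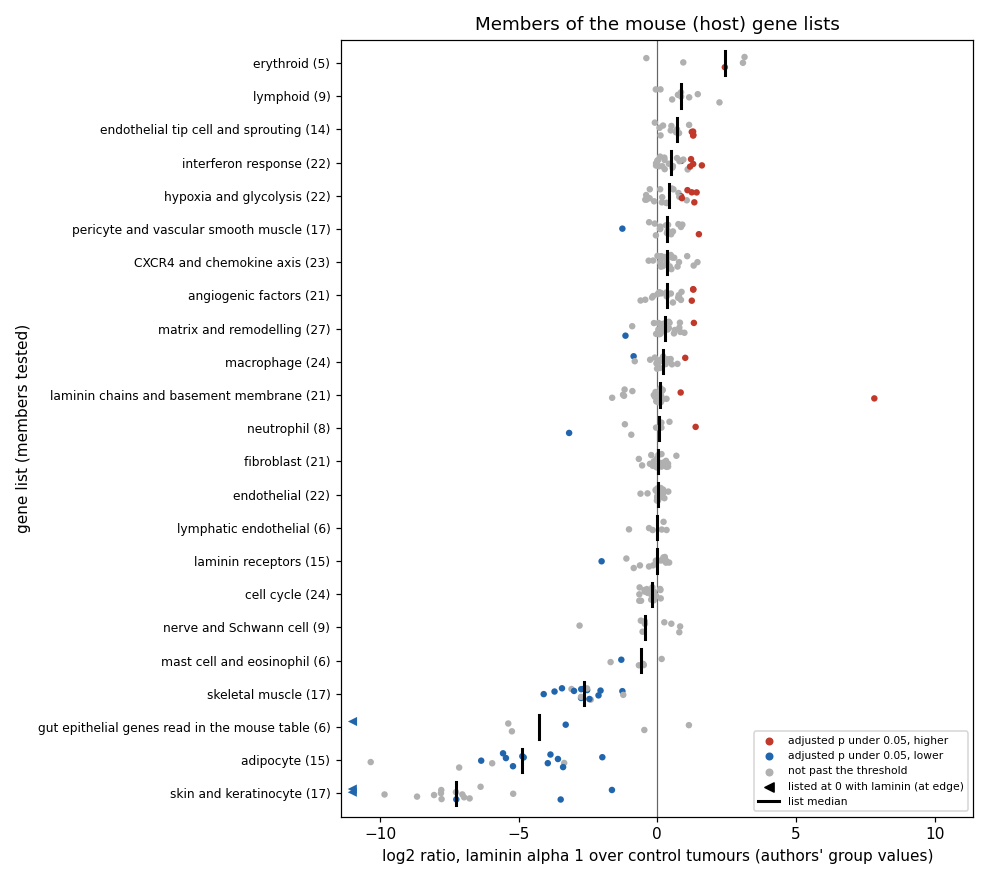
Each point is a tested member of a mouse gene list, placed on the x axis by its log2 ratio of laminin over control tumours, with the number of tested members beside each list on the y axis; triangles at the edge are genes listed at 0 in laminin tumours. Red and blue points passed the authors' q-value threshold, grey points did not, and the black bar is the list median, at -4.87 for adipocyte, -2.65 for skeletal muscle and 0.69 for tip cell genes.

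Genes higher in both species, and genes lower in both, were more frequent than independent calls would give. Among 9473 symbols tested in both tables, 38 were higher in the host and 841 in the tumour cells, and 16 were higher in both, against 3.37 for independent calls (odds ratio 7.59, exact two-sided Fisher test, adjusted p = 1.77e-07 over 4 tests, across genes). They included the hypoxia genes SLC2A1, ERO1L, NDRG1, ADM and SLC16A3, the interferon genes IFIT1, ISG15 and RSAD2, and the chemokine CX3CL1, which had 85.1 and 155 ppm in the host. Lower in both were 20, against 8.77 (odds ratio 2.49, exact Fisher test, adjusted p = 0.00121), among them ACACA, SQLE, LSS and INSIG1. The host log2 ratios of these 4 genes were -3.41, -1.49, -1.84 and -1.21, and those in the tumour cells were -0.42, -0.48, -0.41 and -0.46. These 20 also held CIDEC and TNNI2 of the host's adipocyte and muscle lists, and 4 of the 20 were listed at 0 in the host in laminin tumours. The lists hold only some fat, muscle and skin genes. How many of the 20 belong to the host's fall of such genes was not tested. Lower in the host and higher in the tumour cells were 29, against 19.6 (odds ratio 1.57, exact Fisher test, adjusted p = 0.0409), a result that passes neither without a level minimum (adjusted p = 0.0805) nor at 5 ppm (adjusted p = 0.0571). Higher in the host and lower in the tumour cells were EGR1 and TOR3A, 2 genes against 1.51 (exact Fisher test, adjusted p = 0.663).

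**Figure D3:**
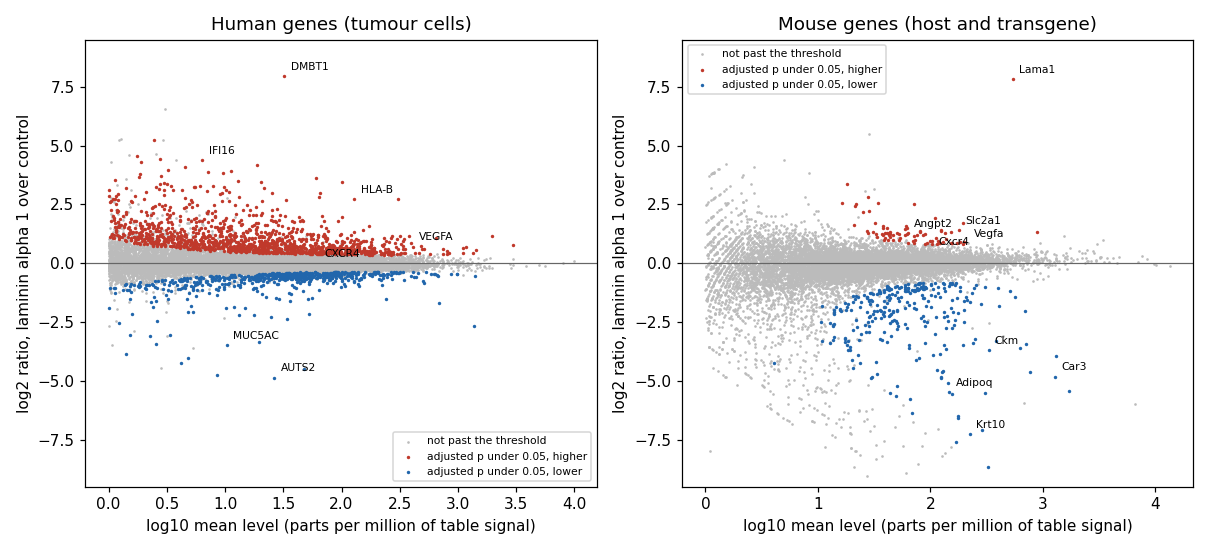
Each point is a tested gene with signal in both groups and a mean level of at least 1 ppm, placed by the log10 of its mean level in ppm (x axis) and its log2 ratio of laminin over control tumours (y axis), for human genes on the left and mouse genes on the right. Red and blue points passed an adjusted p under 0.05; Lama1 stands at a log2 ratio of 7.82 in the mouse table and DMBT1 at 7.97 in the human table.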

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

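Leaving out genes listed at 0 in a group, and leaving out adipocyte, skeletal muscle and skin genes, were chosen after the data were seen, and the other alternatives beforehand. With no level minimum and at 5 ppm, the 17 lists past the Fisher threshold kept their side of it and the sign of their median in 34 of 34 values, and the 23 other lists stayed short of it in 46 of 46. Among these others, medians near 0 or over few members turned sign. At 5 ppm the human chemokine axis turned to -0.0413 (3 members), unfolded protein response to 0.00251, lymphatic endothelial to 0.159 (5 members) and nerve genes to 0.378 (6 members), and with no minimum neutrophil genes turned to -0.0454. With centred ratios unfolded protein response turned to 0.0206, laminin receptors to 0.0200 and lymphatic endothelial to 0.0259. A pseudocount or centring cannot change which genes pass, since the calls rest on the authors' p-values, and so shows nothing about their stability. Of 115 named genes that passed and have a finite ratio, the fold moved by over 1.5 times for 20 with a pseudocount of 1 ppm and for 4 with 0.1 ppm, because low levels weigh more, and DMBT1 went from 251-fold to 52.1-fold with 1 ppm. Counts that moved by over 1.5 times did so by construction, since fewer genes could pass. In the human table, changes of at least 2-fold left 867 genes, 718 higher and 149 lower. At 5 ppm 921 human genes were higher, and an adjusted p under 0.01 left 385 lower. In the mouse table an adjusted p under 0.01 left 44 higher genes, and without genes listed at 0 there were 282 lower, while without fat, muscle and skin list genes there were 397 lower. The share of calls that were higher ranged from 65.2% to 82.8% in the human and from 12.7% to 22.1% in the mouse table, and the 2-fold setting gave the highest human share against 69.7% as reported. Of the 4 ortholog overlaps, that of genes lower in the host and higher in the tumour cells had an odds ratio of 1.45 (exact Fisher test, adjusted p = 0.0805) with no level minimum and 1.66 (adjusted p = 0.0571) at 5 ppm, and the cause was not tested. Leaving out each tumour in turn, a covariate for sample name style, camera with an estimated correlation and other splits of the tumours were not run, because the tables hold group values only. No paired analysis was possible because the columns carry no tumour. At the depth estimated from read steps, 1 read was worth 0.103 to 0.254 ppm in the mouse and 0.0120 to 0.0137 ppm in the human table. Of the 143 called mouse genes listed at 0 in laminin tumours 39 had at most 25 reads in control tumours, so low host genes listed at 0 could still be called. These genes do not show whether low host genes with reads in both groups could be called.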

Other observations

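The families in this paragraph and the next were chosen after their members had been seen to move, so their counts are given without a test, and all tests of explanations in this part were also chosen after the result was seen. Of 10 tested HLA genes and pseudogenes 7 rose and 0 fell in the tumour cells, 2 of the 7 being pseudogenes (HLA-H and HLA-V), while the class II genes HLA-DMA and HLA-DOB did not pass. HLA-B went from 34.0 to 225 ppm, HLA-C from 84.3 to 223 ppm and HLA-F from 10.9 to 38.7 ppm, with the reservation that these genes share reads with each other and with the pseudogenes. All 4 tested MAGE cancer-testis genes rose. MAGEA3 (4.18 to 38.6 ppm), MAGEA6 (5.65 to 45.2 ppm) and MAGEA12 (3.35 to 37.1 ppm) are near copies, so their separate values are uncertain. Of 8 metallothionein genes and pseudogenes 4 fell, including MT2A (25.8 to 11.5 ppm) and MT1E (54.1 to 35.5 ppm). Of 6 CEACAM genes CEACAM7 (16.6 to 183 ppm) and CEACAM1 (146 to 231 ppm) rose and CEACAM6 fell.

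In the host, 3 of 13 immediate early genes rose, Fos (18.7 to 56.6 ppm), Egr1 (91.0 to 185 ppm) and Nr4a1 (25.6 to 53.9 ppm). Among families of skin structure genes, of which some keratins also stand in the fixed skin list, 19 of 20 hair keratin-associated genes fell, and these 19 were listed at 0 in laminin tumours. Keratin genes were called lower in 11 of 31 cases and cornified envelope genes of the Lce and Sprr families in 9 of 11. Genes not called were not thereby unchanged. Among uncalled keratins, Krt71 went from 306 to 1.37 ppm and Krt79 from 122 to 0.254 ppm, while Krt19 was higher (1.84 to 4.05 ppm). The uncalled Lce1f went from 4.95 to 0.169 ppm and Sprr4 from 2.01 ppm to listed at 0.

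Fat, muscle and skin genes fell together in the mouse table. A shift of the whole table was excluded, since its median log2 ratio was -0.0304, and genes listed at 0 were not the cause in the adipocyte and muscle lists, where 0 of 23 falls were listed at 0, nor the whole cause in the skin list, where 3 of 15 genes fell without them (adjusted Fisher p = 0.0220, against 5 of 17 and 8.38e-04 with them). The read steps point to unequal control tumours for genes listed at 0, which include no tested adipocyte or muscle list gene. Of 195 such genes 61 had control values that were whole multiples of the same step and 0 of either other step (12, 6 and 16 of 7270 genes within 2-fold). Among the 67 low genes whose reads could be assigned that tumour held 58.9%, although 34 of the 67 had reads in all 3 control tumours. Genes at least 16-fold lower and not at 0 showed the same lean, with 20 of 141 at whole multiples of that step, against 1 and 0. Of 6 adipocyte and skin list genes low enough 1 was such a multiple. Where 1 control tumour holds the reads of a gene, the control tumours differ among themselves, which an effect of laminin does not predict. That covers only part of the genes listed at 0, and it was not shown for the adipocyte and muscle lists. For the 3 lists, host tissue beside the tumour, collected with control tumours, and an effect of laminin on the surrounding tissue cannot be told apart. The medians of the 3 lists (-2.65 or lower, against 0.03 for endothelial and 0.04 for fibroblast genes) are what the first was drawn from, and either would allow them.

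The fall also shows a property of the deposited calls: of 202 genes listed at 0 in laminin tumours and at 1 ppm or more in control tumours 143 were called, but of 203 genes at least 16-fold lower and not at 0 only 33 were (median unadjusted p = 0.0742 in the authors' deposited table). Scd1, at 12931 and 207 ppm, had q = 0.794 in the authors' deposited table, and Krt5, at 269.6 and 1.02 ppm, had q = 0.258 in the authors' deposited table.

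Orthologs rose in both tables, 16 in number, which human reads counted in the mouse table might produce. In laminin tumours, where such reads would have to appear, the mouse level of 14 gut epithelial genes abundant in the tumour cells was at most 0.446% of the human level (median 0.151%). To account for the shared rises, 2.64% or more of the human level would have had to appear in the mouse table, with a median of 70.2%, so that 16 of 16 lay above the highest share seen in laminin tumours. In control tumours the highest share was 4.76%, for Cdh1, which fell in the host, and 15 of 16 lay above it. All these are shares of ppm levels on unlike scales, not of reads. A read is worth 0.103 to 0.254 ppm for mouse genes and 0.0120 to 0.0137 ppm for human genes, so shares of reads would be smaller. The needed and seen shares in laminin tumours are on the same scale, so their order stands. An effect of laminin on both tumour and host cells stays open and was not tested.

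Interferon genes rose in the tumour cells, which mouse reads counted in the human table could in principle produce. Of the 21 genes that rose, 4 had no mouse gene of the same symbol with signal, and 17 of 17 others needed a larger share of the mouse level (lowest 13.7%, median 34.6%) than the highest seen for 12 host stroma genes in laminin tumours, 13.5% for CD68, with a median of 0.0632% over the 12. The lowest of these lies close to that bound, and CD68 may be expressed by the tumour cells themselves. Human LAMA1 stood at 0.0908% of mouse Lama1 in laminin tumours. Whether the grafted cells of both groups differed in other ways than laminin cannot be told apart from an effect of laminin: of 95 human genes called higher from 0 whose reads could be assigned, 75 had reads in all 3 laminin tumours, as either would give.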
